A study of Xenopus tropicalis with 2 samples.

How the data were processed

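Chromatin immunoprecipitation (ChIP) followed by sequencing was applied to the part of the brain that holds the preoptic area, hypothalamus and thalamus, dissected from wild-type Xenopus tropicalis tadpoles at Nieuwkoop-Faber (NF) stage 62. Per the labels' protocols, tadpoles were reared at 25 °C, chromatin was fixed with formaldehyde and sheared by sonication, and 5 µg per reaction were precipitated with a polyclonal antiserum raised to Xenopus thyroid hormone receptors (TRs). There were 2 samples, 1 TR ChIP library and 1 input library, which was sequenced without immunoprecipitation. Sample groups came from the antibody label. There were no replicates, so no test between groups was possible and no p-value was computed.

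The analysis started from the deposited peak list, with 7848 pairs of a peak and a gene. Per the submitters' processing notes, the tools included fastp 0.20.1, FastQC 0.11.9, BWA 0.7.17, SAMtools 1.13, Picard 2.18.2, deepTools 3.5.1 and MACS2 2.2.6, with no role or order given. The genome build and the peak threshold were not given in the sources used here, and coordinates are those of the deposited list. The deposited enrichment was taken as a linear fold ratio at the peak summit. The deposited values of significance are the −log10 of a p-value and of its adjusted form, and the lowest adjusted value was 1.31. The deposited score equalled 10 times that −log10 adjusted p-value, rounded down, in every peak. Per the deposited annotation, a peak was paired with each gene whose body or 10 kb upstream part held all or part of it. Gene models had start, end and strand only, so exons, introns and UTRs were not distinguished.

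Fold and p-value together gave back the fragments behind each peak. With fold = (ChIP fragments + 1) / (background + 1) and p the upper Poisson tail, a whole number of ChIP fragments solved both values for all 6302 peaks, with a largest misfit of 2.48e-05 in −log10 p (tolerance 0.0001). The solved background lay on whole multiples of 0.6144 fragments, within 0.0005, for 64.9% of peaks, against 0.171% by chance. Of the other peaks, 91.4% lay on the step of a 1 kb window scaled to a fragment of 211 bp, the width of the narrowest peak, against 0.771% by chance. Such steps need whole control tags, each counted as 0.6144, so a control library entered the peak calling. Under MACS2's usual scaling to the smaller library, the control held 1.63 times as many tags as the ChIP library. Total depths are not known. Intervals on ChIP fragments and folds are exact 95% Poisson intervals. They cover counting error of the ChIP fragments alone, leave out the error of the background, and apply to peaks that were selected for being high. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals.

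Gene names needed care. Where a deposited gene description carried an NCBI gene number, the symbol of that number in the reference gene table (assembly UCB_Xtro_10.0, used for names and gene length) was taken. Of 1023 genes with such a number, the deposited name was the same in 542 (53.0%). For 336 genes on chromosomes whose names differed, the deposited name belonged to the same chromosome in 44 (13.1%), and the NCBI number did in 332 (98.8%). Other deposited names were kept only where the description came from Xenbase, RefSeq mRNA, miRBase, UniProt or RFAM. Xenbase names lay on the same chromosome in 99.3% of genes, and names with no description in 15.1%, so the latter were dropped. This left 336 of 5285 genes (6.36%) without a usable name, and 4837 genes were matched to the reference table. Genes with a peak that were not matched could not count for any list.

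The point that stood for a peak was its summit. Peaks were classed as within 1 kb of a transcription start site (TSS), otherwise inside a gene body, otherwise in the rest of a gene region, otherwise outside any gene region. The rest is the upstream 10 kb, together with peaks that overlap a gene end but have their summit beyond it. Shares near a TSS were set against 1000 sets of random positions in the merged regions of the genes that held a peak. For random positions only the TSSs of those genes counted, which can make the random share too low. For gene lists, 21 lists were fixed before the data were examined. A list's count of members with a peak was set against 10000 random lists of the same size, drawn from 15568 named protein-coding genes and matched on gene length in 20 bins. The length of the reference table was used because it covers genes without a peak, and across 4663 genes it followed the deposited gene length (Spearman rho 0.903, across genes, which are not independent replicates). Ties counted at their midpoint in the percentile. Percentiles at or beyond 97.5 and 2.5 are named as outside the random range, and 1.05 of 21 lists would lie there by chance. They describe this 1 peak list and are not p-values. A further 16 gene families, defined by symbol, were added after the peak list had been seen.

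Named genes followed a rule set before the data were examined. It took every gene of the thyroid hormone response list, up to 4 genes with the highest fold in each other list, the 10 named genes with the highest fold and the 10 with the most peaks. Genes named outside the rule are marked as such. Some genes and regions are not reported here.

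The procedures were tested on simulated data. The solver recovered 100% of 6302 simulated whole fragment numbers. Of 400 simulated lists of 20 genes with no change in rate among 15568 genes, 3.50% lay at or above the upper bound and 2.00% at or below the lower one. Lists with 1.5 times the rate passed the upper bound in 27.5% and lists with 2 times the rate in 75.8%, so smaller excesses in lists of this size are often missed. Of 1000 simulated sets of random positions, 96.8% had a share near a TSS inside the random range. These sets used the same TSSs, so they do not test that choice.

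Alternatives covered stricter sets (the 3151 peaks with the higher folds, and the strongest 1000), other windows around the TSS (2.5 kb, and 5 kb for genes), peak centres, nearest genes only, overlap of the peak with the region, no matching on length, −log10 adjusted p-values in place of fold, and assembled chromosomes only. Added after the data were seen were gene lists with peaks near a TSS only, with peaks more than 1 kb from every TSS only, and with names as deposited. No genome of the files' build was used here. The planned searches for the DR4 element and other repeat spacings, the relation of peak strength to DR4, and GC and CpG content were therefore not run. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.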

Results

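TR ChIP signal was measured in part of the tadpole brain at NF stage 62, during the climax of metamorphosis, when thyroid hormone (TH) drives remodelling of the body. TRs are nuclear receptors that bind response elements in DNA and regulate transcription according to the presence of hormone. The data were a list of peaks from 1 TR ChIP library, with 1 input library and no replicates. The 6302 peaks had a median width of 333 bp (range 211 to 4053 bp). Median fold enrichment over background, as the authors' peak caller gave it, was 4.06 (range 2.16 to 36.3). A median of 24 ChIP fragments (range 8 to 172) covered a summit against an expected background of 5.53, so the fold of a typical peak rested on few fragments.

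Most peaks lay in gene bodies or up to 10 kb upstream. The share of the genome in such regions was not known, so no enrichment follows from this. Of the 6302 peaks, 5214 (82.7%, 95% interval 81.8 to 83.7%) fell in the region from 10 kb upstream to the gene end of at least 1 gene, and 1253 fell in regions of 2 or more genes. The peaks covered 5285 genes, of which 4341 (82.1%) had exactly 1 peak and 119 had 4 or more. The gene with the most peaks was bcor, a corepressor of BCL6, with 12 peaks on chromosome 2. The RNA-binding protein gene celf2, the actin-severing factor gene cfl1 and r3hdm1 each had 9. The genes msra.1, snd1 and znf384 each had 8, and bahcc1, cdkal1 and mrpl11 each had 7. Tied with 7 peaks were nr2f1, ssbp4, tubal3.1 and the microRNA gene mir-9-3, which the rule left out by alphabetical order. All 12 peaks of bcor and all 9 of celf2 were paired with no other gene. By contrast, 8 of the 9 peaks of cfl1, all 8 of znf384 and all 7 of mrpl11 were also paired with neighbouring genes, and 1 peak could be paired with up to 10 genes.

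The first question was where the TR ChIP signal sat relative to genes. Peaks concentrated at TSSs. Of the 5214 peaks in gene regions, 3382 (64.9%, 63.6 to 66.2%) had their summit within 1 kb of a TSS, 18.1 times the 3.59% (3.09 to 4.10%) of random positions in the same regions. For random positions only TSSs of genes with a peak counted, so this ratio can be too high. Within 200 bp there were 2100 peaks, and the median distance of TSS-proximal summits was 143 bp. Of the TSS-proximal summits, 1407 lay upstream and 1975 at or downstream of the TSS. The other peaks were 1415 in gene bodies, 417 in the upstream 10 kb or with a summit just past a gene end, and 1088 outside any gene region.

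**Figure D1:**
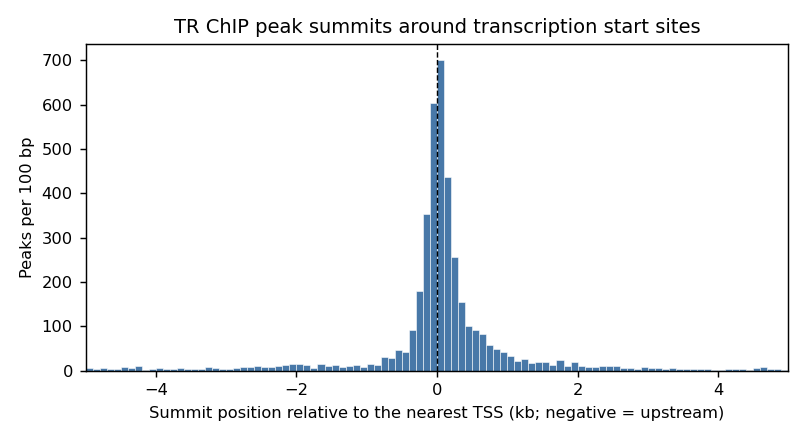
Number of TR ChIP peak summits per 100 bp (vertical axis) by position relative to the nearest TSS in kb (horizontal axis, negative values upstream), for peaks in gene regions. The bars peak at the TSS, where 2100 summits lie within 200 bp.

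Peaks near a TSS and elsewhere had similar folds but different depths. The median fold was 4.15 (quartiles 3.45 to 5.28) within 1 kb of a TSS and 4.02 elsewhere, a ratio of 1.03. Median ChIP fragments at the summit were 28 near a TSS against 20 in gene bodies, and the median background was 6.14 against 4.30. The median −log10 adjusted p-value was therefore higher near a TSS (7.15 against 4.92 elsewhere, a ratio of 1.45). In the 10% of peaks with the highest folds, 468 of 631 (74.2%, 70.6 to 77.5%) were near a TSS. The share fell to 46.1% (42.2 to 50.1%) among peaks with folds of 3.82 to 4.06 and was 57.3% (53.3 to 61.2%) in the weakest 10%, where the median background was highest at 7.37 fragments.

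**Figure D2:**
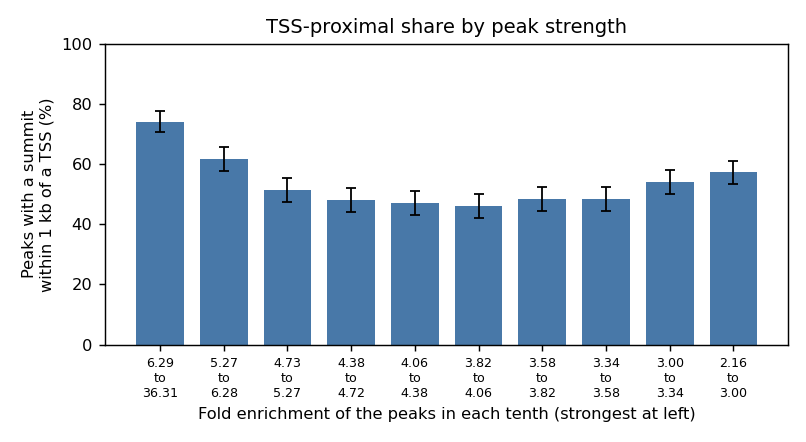
Percent of peaks with a summit within 1 kb of a TSS (vertical axis) in 10 equal groups of peaks ranked by fold enrichment (horizontal axis, strongest at left, with the range of folds), with exact 95% binomial intervals as error bars. The strongest group stands highest at 74.2%, and the middle groups lie between 46.1 and 48.4%.

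The 10 named genes with the highest folds shared 7 peaks, of which 4 lay within 1 kb of a TSS. The highest fold was 36.3 (95% interval 30.8 to 42.5), from 153 ChIP fragments, 9.22 kb upstream of the tight junction gene cldn6.1 on chromosome 9 (7066204 to 7067110). The next peak (19.8, 16.5 to 23.5) lay at the starts of nit1 and pfdn2 on chromosome 8 (117255147 to 117255771), 6 bp from the TSS of nit1 and 198 bp from that of pfdn2, a subunit of the prefoldin chaperone. A peak of 18.3 (15.3 to 21.8) lay upstream of both jmjd6 and mettl23 on chromosome 10. The RNA polymerase subunit gene polr1c had a peak of 17.6 (14.2 to 21.5) at 219 bp upstream of its TSS on chromosome 5. A peak of 17.8 lay on an unplaced scaffold in the regions of rangrf, 182 bp downstream of its TSS, and zpy1. The peaks of cox7a2l (18.9) and elp3 (18.4) lay inside the genes, 5.71 kb and 31.5 kb from their TSSs.

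The second question was whether genes known to respond to TH held TR ChIP peaks. TH response genes held peaks more often than random lists matched on length, in 11 of 20 cases against a median of 6 (95% of lists 2 to 10). The count was 1.90 times the random mean, at percentile 99.2. An excess of this size was not particular to TH response genes. It was 1.96 times for neuronal and synaptic genes and 2.61 times for cytosolic ribosomal protein genes, a family added after the peak list had been seen. For reference, 4656 of all 15568 named genes (29.9%) had a peak. The list had 22 genes, of which hr and st3gal2 could not be matched to the reference table. The TH receptor gene thrb, itself induced by TH, had a peak 88 bp downstream of its TSS on chromosome 6 (77217208 to 77218022) with a fold of 9.25 (6.89 to 12.2), and a second peak 144 kb into the gene (3.77, 2.35 to 5.79). The transcription factor gene klf9 had 5 peaks on chromosome 1. The highest lay 5.93 kb upstream of the TSS (117612576 to 117613864) with 89 ChIP fragments and a fold of 10.01 (8.06 to 12.3). Another klf9 peak, at 333 bp upstream, had a fold of 6.17 (4.75 to 7.88). The intervals of these neighbouring peaks did not overlap. They leave out the error of the background, and the first peak was picked as the highest of 5, so the order is not settled. The leucine zipper gene thibz had 1 peak 4.81 kb upstream on chromosome 3 (129209318 to 129209592), with a fold of 7.79 (4.84 to 11.9) from 19 ChIP fragments. Its background of 1.57 fragments was the lowest of all peaks, and the interval leaves out the error of that background.

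**Figure D3:**
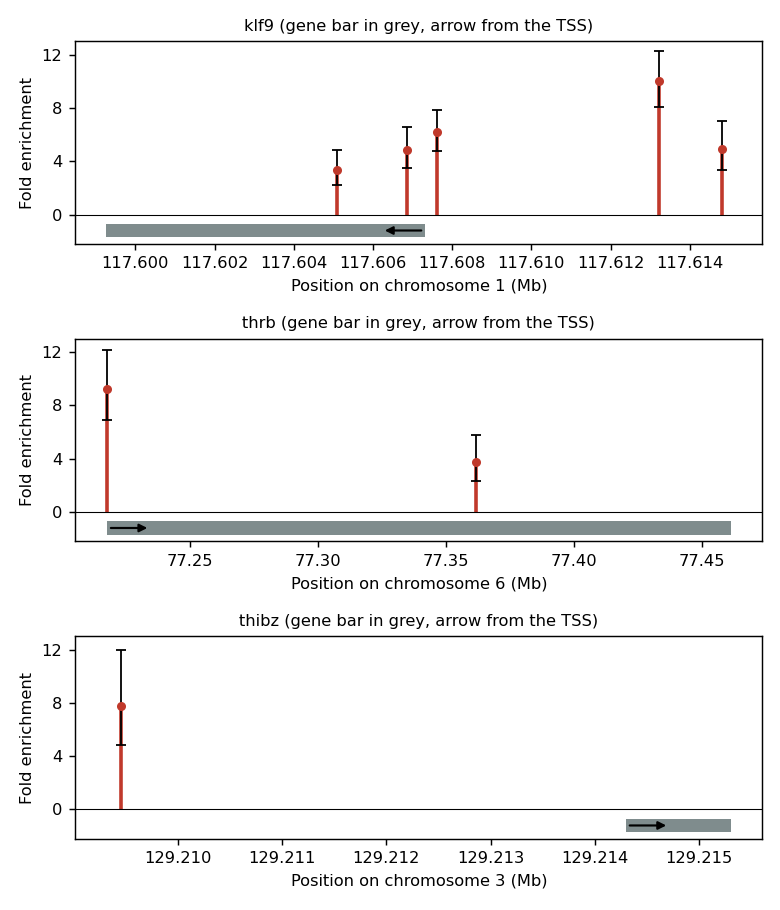
Fold enrichment of each peak (vertical axis, points with 95% Poisson intervals) by chromosome position in Mb (horizontal axis) for klf9, thrb and thibz, with the gene body as a grey bar and an arrow from the TSS. The highest klf9 and thibz peaks lie upstream of the gene, at 5.93 and 4.81 kb, and the highest thrb peak lies at the TSS.

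Other TH response genes with peaks ranged more widely in position. The transcription factor gene sox4 had 6 peaks on chromosome 6, the highest at 247 bp downstream of the TSS (4.79, 3.34 to 6.67). The arginine methyltransferase gene prmt1 had a peak 275 bp downstream of its TSS (6.0, 4.33 to 8.12), and the histone H3K79 methyltransferase gene dot1l had one 643 bp upstream (3.38, 2.51 to 4.45). The de novo DNA methyltransferase gene dnmt3a had 2 intragenic peaks on an unplaced scaffold, the higher 26.4 kb from its TSS (4.75, 3.25 to 6.71). The genes myc, bcl6 and gadd45g had 2 peaks each, with highest folds of 4.13, 4.68 and 4.53. The calcineurin regulator gene rcan2 also had 2, the higher 236 kb into the gene on chromosome 5 (6.33, 3.78 to 10.05) from 16 ChIP fragments over a low background of 1.69. No peak was listed for mmp11, dio3, shh, mecom, crhbp, mafb, nfil3, hes1 or tgm2. A peak at a gene entry without a usable name (336 of 5285 genes) would be missed here. With only peaks more than 1 kb from every TSS, 9 of 20 TH response genes kept a peak against a random median of 1, above all 10000 random lists. With only peaks within 1 kb of the TSS the count was 8 and the percentile 96.9, inside the random range.

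Lists of coregulators, histone modifying enzymes and Kruppel-like factors also held more genes with a peak than random lists did. Nuclear receptor coregulators held peaks in 18 of 24 genes, 2.38 times the random mean and above all 10000 random lists. The highest folds were at tbl1xr1, a subunit of the NCoR corepressor complex (7.55, 5.42 to 10.2, 69 bp upstream of the TSS), the coactivator gene ncoa3 (6.60, 17.7 kb into the gene), prmt1 and ncoa1 (5.98). Histone modifying enzymes held peaks in 24 of 35 genes (2.27 times, above all 10000 lists), led by the H3K4 methyltransferase genes kmt2b (13.1, 10.3 to 16.4), kmt2d (9.89, 7.65 to 12.6) and setd1a (8.33, 6.62 to 10.4) and the demethylase gene kdm3a (7.60). Kruppel-like factors held peaks in 8 of 14 genes (percentile 98.2), with klf9 followed by klf6 (5.23), klf10 (5.19) and klf13 (4.72). The percentile of this list was 94.3 among the 3151 stronger peaks, 51.7 among the strongest 1000, 97.4 with centres within 5 kb of the TSS and 94.3 with names as deposited, all inside the random range.

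The series concerns DNA methylation, and the genes of that system were counted as a list. Genes of DNA methylation and demethylation held peaks in 10 of 25 cases, 1.32 times the random mean and inside the random range (percentile 85.3). The highest folds were at mat2a, which makes the methyl donor S-adenosylmethionine (6.92, 5.16 to 9.11), the methylcytosine dioxygenase gene tet3 with 5 peaks (6.60, 4.61 to 9.20), idh2 (6.09) and mbd3 (5.06). Genes of TH transport and metabolism held peaks in 7 of 18 cases (percentile 78.0), with thrb, the partner receptor gene rxrb (8.10, 5.44 to 11.7), slc7a5 (4.44) and slc3a2 (4.34). Among that list, chosen after the values were seen, thra and the deiodinase genes dio1 and dio2 had no listed peak. All nuclear receptors together held peaks in 12 of 48 genes (percentile 15), with rara (5.20) and nr4a1 (5.04) next after thrb and rxrb.

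Lists of cell types found in this tissue differed from one another. Neuronal and synaptic genes held peaks in 40 of 60 cases, 1.96 times the random mean and above all 10000 random lists. The examples were the scaffold gene dlg2 (7.03, 4.38 to 10.8, 190 kb into the gene), the SNARE gene snap25 (6.57, 4.91 to 8.63, 28 bp upstream of the TSS), the tubulin gene tubb3 (6.41) and the glutamate receptor gene gria2 (5.86). The fold at dlg2 came from 19 ChIP fragments over a background of 1.84, and that at snap25 from 50 over 6.76. Among the strongest 1000 peaks this list lay inside the random range (percentile 85.1). Genes of neural progenitors and radial glia held peaks in 15 of 37 cases (percentile 94.8), including id4 (5.94), pax6 (5.70), zic2 (4.91) and id2 (4.72). This list passed the upper bound with each peak given to the nearest TSS alone (98.7). By contrast, hypothalamic and neuroendocrine genes held peaks in 6 of 53 cases, 0.408 times the random mean (percentile 0.225), although the dissected region contains the hypothalamus. With the 3151 stronger peaks this list lay at 2.96, and with peaks more than 1 kb from every TSS at 69.8, both inside the random range. Those with the highest folds were adcyap1 (5.27), dlx5 (5.21), isl1 (5.09) and tcf7l2 (4.92).

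Markers of oligodendrocytes, microglia and vessels, which the brain also contains, and of tissues outside the brain held few peaks. None of 25 genes of oligodendrocytes and myelin, 15 of microglia and macrophages and 29 of liver and gut had a listed peak (percentiles 0.015, 0.250 and 0). Peaks at gene entries without a usable name could not count for any list. Endothelium and blood had 1 of 20, tal1 (3.02, percentile 0.675). Skeletal and cardiac muscle had 3 of 29, actn2 (6.33), myl1 (4.73) and mef2c (3.22), at percentile 0.720. Both peaks of actn2 and all 4 of myl1 were also paired with other genes, and mef2c also acts in neurons. With the strongest 1000 peaks, or with peaks more than 1 kb from every TSS, even a count of 0 would place each of these 5 lists inside the random range (4.05 or higher), so neither setting tests for depletion. With the 3151 stronger peaks the muscle list lay inside it (5.45), and the microglia list held 0 peaks, which cannot lie below 2.59. With peaks within 1 kb of the TSS the endothelium and blood list did (3.55), and with names as deposited the muscle list did (2.62).

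The remaining lists lay inside the random range. Cell cycle and DNA replication had 12 of 46 genes (percentile 28.3), led by orc1 (9.23, 7.52 to 11.2), rbl1 (8.92), cdkn2c (7.27) and aurka (5.93). Of those 12 genes, 7, including orc1, cdkn2c and aurka, had only peaks that were also paired with other genes, and with each peak given to the nearest TSS alone 8 of 46 held a peak (14.2). Apoptosis had 8 of 26 (58.7), led by mcl1 (8.30), aifm1 (7.42) and cflar (7.10). The circadian clock had 7 of 24 (51.1), with clock (4.34), ciart (3.88), csnk1d (3.78) and csnk1e (3.45). Wnt signalling had 10 of 44 (17.2), led by ctnnb1 (7.48) and tcf7 (5.40), followed by tcf7l2 and gsk3b (4.30). Hedgehog signalling had 4 of 21 (14.3), namely iqce (6.72), disp1 (5.97), ptch1 (3.83) and gas1 (3.63). Matrix remodelling had 8 of 31 (26.0), with mmp24 (4.40), mmp14 (4.11), adamts5 (4.09) and timp2 (3.79). Among genes named for the other lists, all peaks of rxrb, setd1a, kdm3a, pax6, id2, aifm1, cflar, iqce and timp2 were also paired with other genes.

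**Figure D4:**
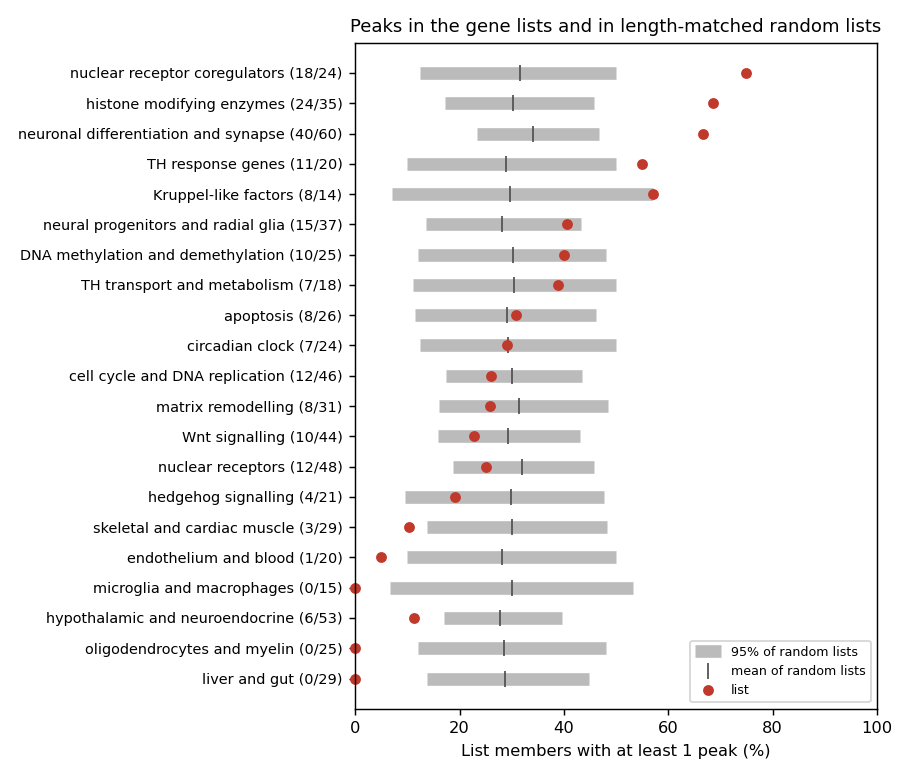
Percent of list members with at least 1 peak (horizontal axis) for the 21 gene lists (vertical axis, with counts), as red points, against the mean (tick) and 95% range (grey bar) of 10000 length-matched random lists. Coregulators, histone modifying enzymes, neuronal genes and TH response genes stand above their range, Kruppel-like factors at its upper end, and 6 lists below.

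Peaks were spread over all chromosomes. Density was 4.78 per Mb (95% Poisson interval 4.66 to 4.90) over all sequences with a peak, each counted to its last gene or peak. It ranged from 3.82 (3.47 to 4.19) on chromosome 7 to 6.59 (5.81 to 7.43) on chromosome 10. On 262 unplaced scaffolds 540 peaks (8.57%) gave 10.7 per Mb (9.78 to 11.6), a value raised because scaffolds without a peak do not enter it.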

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

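Of the 6302 peaks, 1088 (17.3%) lay outside any gene region and so entered no gene comparison. Their median fold was 4.05 and their median ChIP fragments 20, against 3.98 and 20 in gene bodies, so their medians were close to those of intragenic peaks.

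Some of these peaks lay in groups, which drew attention because no gene comparison used them. On chromosome 1, between tmem161b and mef2c and around the microRNA gene mir-9a-2, 14 peaks fell in 170159766 to 170243246, with a highest fold of 6.41, and 8 more in 170021725 to 170120210, between tmem161b and mir-9a-2. On chromosome 7, 10 peaks fell in 112624484 to 112716195, between ppp2r1a and the microRNA gene mir-125a and around let-7a and mir-100. On chromosome 10, 8 peaks fell in 20315302 to 20417177, beside bahcc1. Neighbours are the nearest genes with a peak that lie wholly outside a group. No explanation of these groups was tested.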

How the results depend on the processing

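The settings with peaks near or far from a TSS alone, and with deposited names, were chosen after the data were seen. The share of peaks in gene regions rose from 82.7% to 89.6% in the strongest 1000 peaks. Genes with a peak fell from 5285 to 3137 with the 3151 stronger peaks and 1269 with the strongest 1000, as fewer peaks cover fewer genes; the other 4 region and overlap rules stayed within 1.5 times. The share within 1 kb of a TSS moved from 64.9% to 67.7% with the stronger peaks, 78.0% with the strongest 1000 and 73.0% within 2.5 kb, a wider window. The ratio of medians near a TSS to elsewhere was 1.03 by fold and 1.45 by −log10 adjusted p-value, which also grows with depth. Density was 4.54 peaks per Mb on assembled chromosomes alone.

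Of 21 lists, 5 lay above and 6 below the random range. With the stronger peaks 3 lay below, and with the strongest 1000 it was 3 above and 1 below. Without matching on length all 21 kept their side. With peaks more than 1 kb from every TSS 0 lay below, but there, as with the strongest 1000, a count of 0 would leave 5 of the 6 inside the range. The hypothalamic list moved from percentile 0.225 to 69.8 with distal peaks, and the cause was not tested. The TH response list passed in all settings except peaks within 1 kb of the TSS (96.9), cause not tested.

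Searches for DR4 and other repeats, the relation of strength to DR4, GC and CpG content, with every alternative listed for them, were not run, since they need a genome. No paired analysis was possible because each group held 1 library. Depth limits folds of single peaks: at 19 ChIP fragments, the fold of 7.79 at thibz had an interval of 4.84 to 11.9.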

Other observations

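Gene families added after the peak list had been seen differed widely in their share of genes with a peak. Cytosolic ribosomal protein genes held a peak in 68 of 85 cases (80.0%, 95% interval 69.9 to 87.9%), 2.61 times the mean of length-matched random lists. Translation initiation factors had 32 of 49 (2.23 times), proteasome subunits 25 of 39 (2.14 times), Mediator subunits 18 of 30 (2.04 times), mitochondrial ribosomal proteins 41 of 76 (1.84 times), RNA polymerase subunits 15 of 29 (1.81 times) and vesicle tethering complexes 30 of 55 (1.77 times). All of these lay above the random range. RNA polymerase subunits lay inside it with centres within 5 kb of the TSS (percentile 93.9), with peaks within 1 kb of the TSS (96.9) and with names as deposited (93.0), and Mediator subunits with the strongest 1000 peaks (95.2). With peaks more than 1 kb from every TSS, all but the RNA polymerase subunits lay inside it (30.5 to 96.0). General transcription factors (19 of 44, percentile 96.7), complex I genes (18 of 43, 97.0) and voltage-gated calcium channels (12 of 26, 88.6) lay inside the random range. General transcription factors passed it with the 3151 stronger peaks (98.7), the strongest 1000 (99.7), the nearest TSS alone (98.1) and peaks within 1 kb of the TSS (99.04). Complex I genes passed it with the stronger peaks (98.2), centres within 5 kb (98.3) and peaks within 1 kb (98.8).

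Among other families, none of 36 Hox genes and none of 35 odorant receptor genes had a listed peak (percentiles 0 and 0.010). Here too, gene entries without a usable name could not count. Random lists drew genes singly, so members that lie side by side, as Hox genes do, were treated as independent. These percentiles therefore overstate the evidence for depletion in such families. Solute carriers had 65 of 349 (0.637 times the random mean, below all 10000 random lists). Solute carriers lay inside the random range with the strongest 1000 peaks (2.58) and with peaks more than 1 kb from every TSS (16.7). In these settings Hox and odorant receptor genes again had no peak, which cannot lie below 3.01, so neither setting tests for depletion there. Potassium channels had 21 of 92 (percentile 2.96), Fox genes 9 of 46 (14.8) and Sox genes 5 of 20 (41.7), all inside the random range. Potassium channels fell below it with the 3151 stronger peaks (9 of 92, 1.51), with centres within 5 kb of the TSS (11 of 92, 0.145) and with peaks within 1 kb of the TSS (6 of 92, 0). With peaks more than 1 kb from every TSS, neural progenitor genes had 11 of 37 (percentile 99.995) and neuronal genes 30 of 60, above all 10000 random lists. Peaks with TSSs on both strands within 1 kb of the summit made up 435 (12.9%) of TSS-proximal peaks. Their median fold was 4.59 against 4.11 at TSSs on 1 strand, and they made up 22.1% of the TSS-proximal peaks among the 630 peaks with the highest folds.

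The tests that follow, on the concentration at TSSs and on TH response genes, were chosen after the results were seen. More power to call peaks where background coverage is high could place weak peaks at TSSs. In the 630 peaks with the highest folds, 80.8% of those in gene regions were near a TSS, against an upper bound of 5.19% for random positions. The concentration was therefore not confined to weak peaks. The bound was too weak to weigh power itself. Even the group with the lowest share, with folds of 3.82 to 4.06, had 46.1% of its peaks near a TSS. The part that power plays is therefore not settled. Signal of the ChIP library at active promoters in general remains open. A peak within 1 kb of the TSS was present in 61.2% (49.99 to 71.6%) of cytosolic ribosomal protein genes, 22.1% of all named genes and 40.0% of TH response genes. Receptor binding at such promoters and a less specific recovery of active chromatin may both contribute, and no library with another antibody was analysed here. No biological explanation was tested.

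For the excess of peaks at TH response genes, peaks within 1 kb of a TSS were not the only source. With peaks more than 1 kb from every TSS the list reached percentile 100. Active promoters cannot be set aside by this, because the rule keeps promoter flanks and knows 1 TSS per gene. The distal peaks of bcl6, gadd45g and myc lay 1.34, 1.87 and 2.26 kb from the TSS. Those of sox4 lay 1.41 to 4.30 kb from the TSS, the farthest across the end of this short gene. Those of dnmt3a, klf9, rcan2, thibz and thrb reached 4.81 kb or farther. A broader alternative is that genes active in this tissue hold more distal peaks, whatever their response to TH. Against random lists matched on length and on a peak at the TSS, 9 of 20 TH response genes with a distal peak was 5.15 times the mean of 1.75, again at percentile 100. That bound proved too weak to exclude the alternative, because 5 other lists passed it as well. These were Kruppel-like factors (4.70 times), progenitors (11 of 37, 3.42 times, percentile 99.995), neuronal genes (30 of 60, 2.80 times), coregulators (2.46 times) and histone modifying enzymes (2.05 times). The hypothalamic list did not (percentile 75.4). TH response and other properties of active genes therefore cannot be told apart as the source of the excess, as no expression measurement was analysed here. A candidate explanation for the distal peaks at klf9 and thibz is receptor binding at upstream elements, which needs sequence to test.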
